A study of Mus musculus with 31 samples.

How the data were processed

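The samples were 31 ATAC-seq libraries of Tregs sorted from mouse spleen after an injection of mIL-2 (IL2), mIL-2/CD25 (FP) or PBS. Per the submitters' processing notes and the series design text, reads were mapped to GRCm38 (also given as mm10) with bwa-mem, peaks were called with MACS2 2.1.2, and peaks were kept by the irreproducible discovery rate between 2 pseudo-replicates of each sample. The read counter, any filter on duplicate reads and the way one common peak set was made are not given in the sources used here. The deposited file gives a read count for each of 104979 peaks in each library, with no normalization. The first of the per-sample columns, listed as an other unit in the record of the deposited units, also holds whole-number counts. Commas inside the gene names of 9561 peaks shift it when lines are split at commas, so fields were taken from the right-hand end of each line. The authors' own test, per the series design text, was DESeq2 at p under 0.05.

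Groups were taken from the sample titles. The treatment protocol in the labels gives 0.75 h for every sample, so the later times rest on the titles and column names. At 16 h the columns name the group but use other numbers than the sample titles, so those libraries were matched to groups only and are called c1, c2 and c3. No per-sample column was left unmapped (0). The labels mention 2 technical replicates per biological sample, and the titles of the 168 h samples mention 2 runs. Those replicates are not separate in the deposited table. Peaks were assigned to genes by the deposited annotation, in which 29422 peaks are labelled promoter, 33522 intron, 32223 intergenic, 6685 3' end and 3127 exon. It was checked against GENCODE M21: 84.8% of promoter-labelled peaks and 2.15% of the others lay within 1 kb of an annotated transcription start site, and 97.3% of the gene names were GENCODE symbols. Peaks had a median width of 366 bp, and 35398 overlapped another peak, leaving 73159 regions after merging.

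Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. For each time point, all its groups were fitted together with TMM factors, a filter by filterByExpr (minimum count 10, minimum total 15) and edgeR's quasi-likelihood F test, and p was adjusted by Benjamini-Hochberg over all tested peaks with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Log2 fold changes are those returned by the quasi-likelihood fit. A prior count of 2 was used only for log2 CPM values, as in the offsets and the scores per library. Differences of effects between times came from one fit of all 31 libraries with 1 coefficient per group. The biological coefficient of variation was 43.3%, 41.0%, 38.6% and 48.0% at 0.75, 16, 72 and 168 h, with 6, 6, 4 and 5 residual degrees of freedom. Between libraries of one group, chi-square per degree of freedom ran from 5.10 to 35.7 where counting error alone gives 1. Self-tests on simulated counts with the same spread recovered 50% to 70% of 4-fold changes and 2% to 15% of 2-fold changes in the comparisons with PBS. The changed peaks were drawn from those with a mean log2 CPM above 1, so these shares do not hold for rarer peaks. Unchanged peaks were called too, from 2 for IL2 to 13 for FP at 168 h. The share of such false calls was above 0.05 in each FP comparison and below it in each IL2 comparison, from 1 simulation each. Simulated peaks varied independently, so they lack the trend with library total that many peaks followed at 72 h and 168 h. The recovered shares and false calls need not hold for the data of those times.

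Before the data were examined, 18 gene lists (262 genes, 249 with a peak), 15 motifs, the design of each test, the rule for named genes and the main alternatives were fixed. The lists were IL-2 and STAT5 response, Treg identity, effector Treg, resting and lymphoid-homing T cell, AP-1 and immediate early, NF-kB and TNF receptor, cell cycle, chemokine receptor and trafficking, mTORC1 and MYC metabolism, interferon response, T cell receptor signalling, helper T cell lineage and cytokine, constitutive gene, and markers of B cells, CD8 T cells, NK cells, myeloid cells and erythroid cells. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, two-sided, with Benjamini-Hochberg over the lists of a comparison. List counts are given over all peaks and adjusted over the list alone. Promoter shares used Fisher's exact test. Motifs were searched on both strands of the peak sequence and tested in a logistic model with GC content, width and mean abundance, in comparisons with at least 20 called peaks of a direction.

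Peaks named in a comparison with PBS were the 5 largest rises and 5 largest falls past the threshold with separated groups and a mean log2 CPM of at least 1, 1 peak per gene. To these came up to 4 called members of each list and 1 fixed peak of each of 14 genes followed at every time. For each of these genes it was the peak with the smallest p over all groups in the fit of all 31 libraries. For FP against IL2 only the first part applied, so Gad2, Bcl2, Cdk6, Nfkb1, Il2rb and Hbb-bt were named there after their values were seen. The same holds for Gad2, Cdk6 and Nfkb1 wherever they are named in a comparison in which they did not pass, and for every peak named from the fits with library total as a covariate. The called peaks of IL2 at 0.75 h and FP at 16 h were followed in other comparisons as sets with limma's fry, adjusted over 42 tests within a time and 18 between times, with the tests that contain the comparison used to choose the set left out. fry tests whether a set moves one way on balance and does not compare it with other peaks.

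The alternatives were other scalings (library totals, DESeq2 size factors, an offset by abundance, an offset by GC content), no filter on low counts, DESeq2 as the test, the replicate number as a block, fits with 2 groups or all 31 libraries, promoter peaks only, and leaving out each library. Added after seeing the data were limma's voom with library quality weights, 1 peak per overlapping region, removal of the 15 peaks that each hold over 0.2% of counts (37.6% together), removal of the 2 libraries that stand apart, the sets without the STAT5 consensus, and log2 library total as a covariate in the fit of each time point. Treatment labels were also reassigned, in all 10 splits of 3 against 3 libraries, all 35 of 3 against 4, and 40 random draws with seed 11 for each difference between times, which used only the libraries of the groups involved. The correlation from shared PBS libraries was simulated 20 times without any effect. Raw reads were not analysed here.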

Results

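Chromatin accessibility was measured by ATAC-seq, which counts transposase insertions in open DNA, in regulatory T cells (Tregs) sorted from the spleens of RFP-FoxP3 reporter mice on the C57BL/6 background. The mice had received 5 µg of mouse IL-2 (labelled mIL-2, here IL2), 20 µg of a fusion of mouse IL-2 with CD25 (labelled mIL-2/CD25, here FP) or 100 µL of PBS. PBS, IL2 and FP groups of 3 libraries each were present at 0.75 h and at 16 h. At 72 h there were 3 PBS and 3 FP libraries, and at 168 h 3 PBS and 4 FP libraries, which made 31 libraries in 10 groups. The deposited table gave whole-number counts for 104979 peaks, and library totals ranged from 7.39 to 59.6 M counts (M, mega). The group means of these totals were 23.5, 25.5 and 30.0 M for PBS, IL2 and FP at 0.75 h and 20.0, 33.4 and 26.0 M for the same groups at 16 h. They were 36.2 and 41.9 M for PBS and FP at 72 h and 18.2 and 29.3 M for PBS and FP at 168 h. A single peak on chromosome 1 (24611561-24615794, GRCm38) held 24.0% of all counts, and its share ranged from 15.0% to 32.2% between libraries. PBS replicate 1 and FP replicate 2 at 168 h, with 7.39 and 12.3 M counts, stood apart from the other libraries, with mean correlations of log2 counts of 0.732 and 0.774. Each time point carries its own date in the sample ids, and what was done on that date is not known here. Time and date cannot be told apart, so every effect was taken against the PBS group of the same time. The labels do not say that the libraries came from separate animals, so each p below measures the spread between these samples.

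The first comparison asked which regions opened or closed 0.75 h after IL2. Accessibility rose at 490 peaks in 388 separate regions and fell at 9 peaks among 100468 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; IL2 and PBS, n = 3 each). A peak in an intron of Bcl2, which encodes an inhibitor of apoptosis, rose from 6.79 ± 1.20 to 29.9 ± 2.88 counts per M (CPM, mean ± SD), a log2 fold change of 2.14 ± 0.22 (SE; adjusted p = 2.9e-04). Peaks in Nfkb1, which encodes a subunit of NF-kB, and in Cdk6, which encodes a kinase of cell cycle entry, rose by 2.05 ± 0.24 and 1.99 ± 0.24 on the log2 scale (adjusted p = 7.0e-04 and adjusted p = 0.00101). The 5 largest rises among the more abundant peaks were at Sept9, which encodes a cytoskeletal septin (4.19 ± 0.50), Ccdc71l (3.99 ± 0.82), the noncoding RNA gene Lncpint (3.42 ± 0.54), Nck1, which encodes a signalling adaptor (3.39 ± 0.71), and Ptpn1, which encodes a tyrosine phosphatase that acts on JAK kinases (3.29 ± 0.44). The Bcl2 peak lies on chromosome 1 (106606895-106607640), the Nfkb1 peak on chromosome 3 (135604427-135605216) and the Cdk6 peak on chromosome 5 (3477644-3478642). The deposited annotation calls the Bcl2 and Nfkb1 peaks promoter, while GENCODE M21 places them in introns, 64952 and 62583 bp from the nearest annotated transcription start site.

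Among the falls at 0.75 h after IL2, the largest by the naming rule was at Cntn6, which encodes a neural adhesion molecule (-2.43 ± 0.53). Smaller ones were at Zc3h12c (-1.58 ± 0.34), 1700011L03Rik (-1.46 ± 0.32), Gm20139 (-1.14 ± 0.24) and the very abundant Gm10800 (-0.22 ± 0.05). All 499 called peaks had IL2 libraries wholly above or wholly below the PBS libraries. Over all tested peaks that share was 11.4%, where chance gives 10%. The count of 499 became 220 without PBS replicate 1, 187 without PBS replicate 3, 207 without IL2 replicate 1 and 202 without IL2 replicate 3. The number of falls in such fits, which need not be the same peaks, was 2 without PBS replicate 1, 5 without PBS replicate 2, 0 without PBS replicate 3, 1 without IL2 replicate 1, 11 without IL2 replicate 2, 1 without IL2 replicate 3, and 8, 5 and 9 without FP replicates 1, 2 and 3. With library total as a covariate, added after the data were seen, 286 peaks rose and 0 fell (5807 peaks at an unadjusted p under 0.05, rises and falls together). DESeq2 called 1116 peaks, 96 of them falls.

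The gene lists fixed in advance moved as follows at 0.75 h after IL2. In the IL-2 and STAT5 response list, 6 of 207 peaks rose (13 adjusted over the list alone), 5 of them at Bcl2 and 1 at Lta, which encodes lymphotoxin alpha (1.99 ± 0.41). The list as a set shifted up by camera (adjusted p = 1.9e-06, and adjusted p = 0.734 with an estimated correlation). In the Treg identity list 4 of 212 peaks rose (9 adjusted over the list alone), at Nt5e, which encodes the adenosine-forming enzyme CD73 (4.06 ± 0.59), Nrp1, which encodes the receptor neuropilin (2.70 ± 0.48), Izumo1r (2.62 ± 0.52) and Ikzf2, which encodes the transcription factor Helios (1.92 ± 0.38). That list also shifted up (adjusted p = 5.5e-04, and adjusted p = 0.734 with an estimated correlation). In the resting and lymphoid-homing T cell list 9 of 337 peaks rose (26 adjusted over the list alone), among them peaks at Lef1 (3.15 ± 0.46) and Bach2 (1.38 ± 0.20), which encode transcription factors of resting T cells, at the homing receptor gene Ccr7 (2.47 ± 0.40), and 5 overlapping peaks of Foxp1. Its set test gave adjusted p = 0.00473 upward (adjusted p = 0.776 with an estimated correlation). It pointed downward on promoter peaks alone (median -0.0724, adjusted p = 0.417). In the NF-kB and TNF receptor list 5 of 157 peaks rose (9 adjusted over the list alone), at Nfkb1, Nfkbiz, which encodes a nuclear regulator of NF-kB (1.84 ± 0.31), and Birc3, which encodes an inhibitor of cell death (1.36 ± 0.26). The set test gave adjusted p = 0.00473 upward (adjusted p = 0.776 with an estimated correlation).

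Constitutive genes, kept as a reference list, shifted up too (0 of 47 peaks rose, 1 adjusted over the list alone; median log2 fold change 0.16; adjusted p = 0.00883, and adjusted p = 0.734 with an estimated correlation). Myeloid marker peaks lay lower as a set (0 of 38 peaks fell, 0 adjusted over the list alone; median -0.39; adjusted p = 0.00583, and adjusted p = 0.734 with an estimated correlation). Of the lists with no set-level call, the cell cycle list had 2 of 93 peaks rise (2 adjusted over the list alone), both at Cdk6. The chemokine receptor and trafficking list had 1 of 186 rise (2 alone), at Itga4, which encodes an integrin chain of lymphocyte homing (1.69 ± 0.28). The T cell receptor signalling list had 1 of 281 rise (2 alone), at Prkcq, which encodes a kinase downstream of the T cell receptor (1.86 ± 0.36). The mTORC1 and MYC metabolism list had 1 of 70 fall (1 alone), at Hif1a, which encodes a hypoxia-response factor (-2.60 ± 0.56). In the erythroid cell list 1 of 40 peaks rose (10 alone), at the beta-globin gene Hbb-bt (2.18 ± 0.29), with the list's median at -0.15, its mean at 0.02 and its test upward (adjusted p = 0.531). The effector Treg, AP-1 and immediate early, interferon response, helper T cell lineage and cytokine, B cell, CD8 T cell and NK cell lists had 0 peaks called over all peaks and 0 adjusted over the list alone, with set-level adjusted p between 0.0983 and 0.607.

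Several classical IL-2 targets fixed for follow-up did not pass the threshold at 0.75 h. The Foxp3 peak (chromosome X, 7583723-7584442; the lineage factor of Tregs) had a log2 fold change of 0.99 ± 0.24 (adjusted p = 0.0964). The Il2ra peak, at the gene for CD25, had 0.92 ± 0.28 (adjusted p = 0.271), and the peak at Cish, which encodes a suppressor of cytokine signalling, had 1.59 ± 0.44 (adjusted p = 0.181). Values at Socs2, Myc, Ccnd2, Klrg1, Prdm1, Icos and Tcf7 lay between -0.32 and 0.67, with adjusted p of 0.622 or more.

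**Figure D1:**
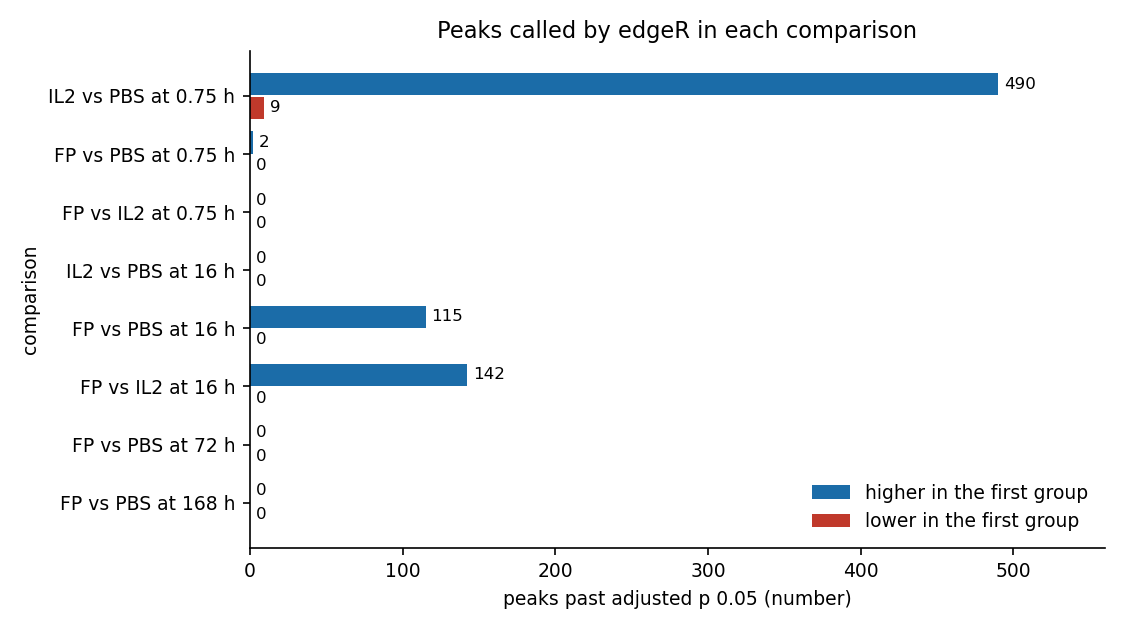
Number of peaks past the threshold (edgeR, adjusted p 0.05) in each comparison, rises and falls apart. IL2 at 0.75 h gave 490 rises and 9 falls, FP at 16 h 115 rises, and FP against IL2 at 16 h 142 rises.

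The risen peaks of IL2 at 0.75 h lay away from promoters and carried a STAT5 sequence. The deposited annotation placed 264 of the 490 in introns, 121 between genes and 47 in promoters. Only 4.69% lay within 1 kb of an annotated transcription start site, against 26.3% of the other tested peaks (odds ratio 0.138, Fisher's exact test, two-sided, p = 2.7e-36). The STAT5 consensus TTCYNRGAA, the palindromic site bound by STAT5 dimers, was present in 346 of the 490 (70.6%) and in 7.11% of the other peaks. Its odds ratio was 16.9 (95% interval 13.7 to 20.8; adjusted p = 1.1e-152) in a logistic model with GC content, width and abundance. Of the 14 other motifs, CTCF was less frequent in risen peaks (0.612% against 6.80%; odds ratio 0.112, adjusted p = 0.00170). NFAT lay in 14.5% of them and in 8.80% of the others, and its odds ratio was below 1 only with GC content, width and abundance in the model (0.661, adjusted p = 0.0208). The rest had adjusted p of 0.0933 or more. The Bcl2 peak held matches at 106607035-106607043 and 106607206-106607214 on chromosome 1, and the Cdk6 peak held one at 3478060-3478068 on chromosome 5. Overlapping peaks are not independent observations, so these intervals and p values are narrower than for independent regions.

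**Figure D2:**
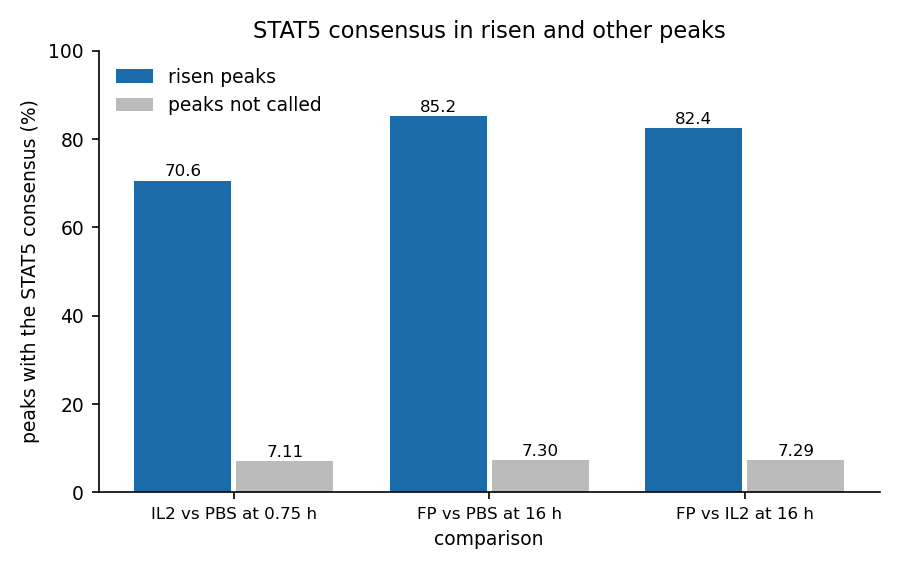
Percent of risen peaks and of other tested peaks that hold the STAT5 consensus. The risen peaks stood at 70.6% (IL2 at 0.75 h), 85.2% (FP at 16 h) and 82.4% (FP against IL2 at 16 h), and the other peaks at 7.11% to 7.30%.

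The same time point was compared for FP. At 0.75 h after FP 2 peaks rose and 0 fell (edgeR, adjusted p under 0.05; n = 3 each): the Bcl2 peak, from 6.79 ± 1.20 to 22.0 ± 0.608 CPM (log2 fold change 1.69 ± 0.22), and an intergenic peak assigned to Gm47635 on chromosome 13 (85502803-85503228), which rose by 1.80 ± 0.23 (adjusted p = 0.0175 for each). Cdk6 had 1.53 ± 0.24 (adjusted p = 0.0554), Nfkb1 1.38 ± 0.23 (adjusted p = 0.0941), Cish 1.17 ± 0.44 (adjusted p = 1) and Foxp3 0.30 ± 0.24 (adjusted p = 1). The count was 25 without FP replicate 3, 1 without FP replicate 1 (a fall, so neither of the 2 rises) and 0 without any of FP replicate 2, PBS replicates 1, 2 and 3 and IL2 replicates 1 and 3, which share the fit. The fit of these 2 groups only, that of all 31 libraries and that with library total as a covariate called 0, DESeq2 called 210 peaks and an unadjusted p under 0.05 was reached by 3160. A fit with replicate number as a block also called more, as given in the part on how the results depend on the processing.

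The IL-2 and STAT5 response list shifted up at 0.75 h after FP (1 of 207 peaks rose, 2 adjusted over the list alone; adjusted p = 0.00480, and adjusted p = 0.979 with an estimated correlation). Erythroid cell markers shifted up in the same comparison (0 of 40 peaks rose, 1 adjusted over the list alone; median 0.41; adjusted p = 3.0e-04, and adjusted p = 0.979 with an estimated correlation). Their test pointed downward on the 7 promoter peaks alone (median -0.17, adjusted p = 0.765). CD8 T cell markers lay lower (0 of 38 fell, 0 alone; median -0.26; adjusted p = 0.00413, and adjusted p = 0.979 with an estimated correlation). None of the other 15 lists passed.

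FP and IL2 were also compared directly at 0.75 h, as regimens, since the doses differ. No peak passed (edgeR; lowest adjusted p = 1; 3677 peaks at an unadjusted p under 0.05; 6 by DESeq2). Bcl2 differed by -0.45 ± 0.21 and Nfkb1 by -0.67 ± 0.23 (FP minus IL2; adjusted p = 1 for each). Over the 115 peaks that rose with FP at 16 h, chosen on other libraries, the median difference at 0.75 h was -0.54 (limma's fry, adjusted p = 0.00307). As a set, FP was lower than IL2 in the resting and lymphoid-homing T cell list (adjusted p = 0.00195, and adjusted p = 0.809 with an estimated correlation), the Treg identity list (adjusted p = 0.00391, and adjusted p = 0.809 with an estimated correlation) and the IL-2 and STAT5 response list (adjusted p = 0.0143, and adjusted p = 0.809 with an estimated correlation). These 3 lists had 0 peaks called, also adjusted over the list alone. Erythroid cell markers were higher as a set with FP (0 of 40 peaks called, 8 adjusted over the list alone; median 0.23; adjusted p = 0.0143, and adjusted p = 0.809 with an estimated correlation). Their test pointed downward on promoter peaks alone (median -0.18, adjusted p = 0.962).

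At 16 h the question was which regions stayed or became open after each protein. With FP 115 peaks in 111 regions rose and 0 fell among 100771 tested (edgeR; n = 3 each). A peak in an intron of Gad2, which encodes a GABA-forming decarboxylase, rose from 2.67 ± 0.822 to 27.6 ± 5.50 CPM, by 3.38 ± 0.29 on the log2 scale (adjusted p = 1.7e-06; chromosome 2, 22679731-22680633). Bcl2 rose by 1.95 ± 0.28 (adjusted p = 0.00263), Cdk6 by 1.80 ± 0.24 (adjusted p = 0.00223) and Itga4 by 1.63 ± 0.29 (adjusted p = 0.0131). Other large rises were at Gm18726 (3.45 ± 0.49), Wwp1, which encodes a ubiquitin ligase (3.08 ± 0.34), Gm43674 (3.08 ± 0.55) and Ppm1l, which encodes a protein phosphatase (2.91 ± 0.46). Cish had 1.60 ± 0.44 (adjusted p = 0.292), Il2ra 0.87 ± 0.29 (adjusted p = 0.533) and Foxp3 0.67 ± 0.28 (adjusted p = 0.840). All 115 peaks separated the groups, against 12.3% of all tested peaks, where chance gives 10%. The count was 48, 61 and 51 without each PBS library and 37, 39 and 66 without each FP library (libraries c1, c2 and c3 in turn). It was 54 with library totals as the scaling, 194 with the 2 groups only, 271 by voom (added after the data were seen) and 452 by DESeq2.

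**Figure D3:**
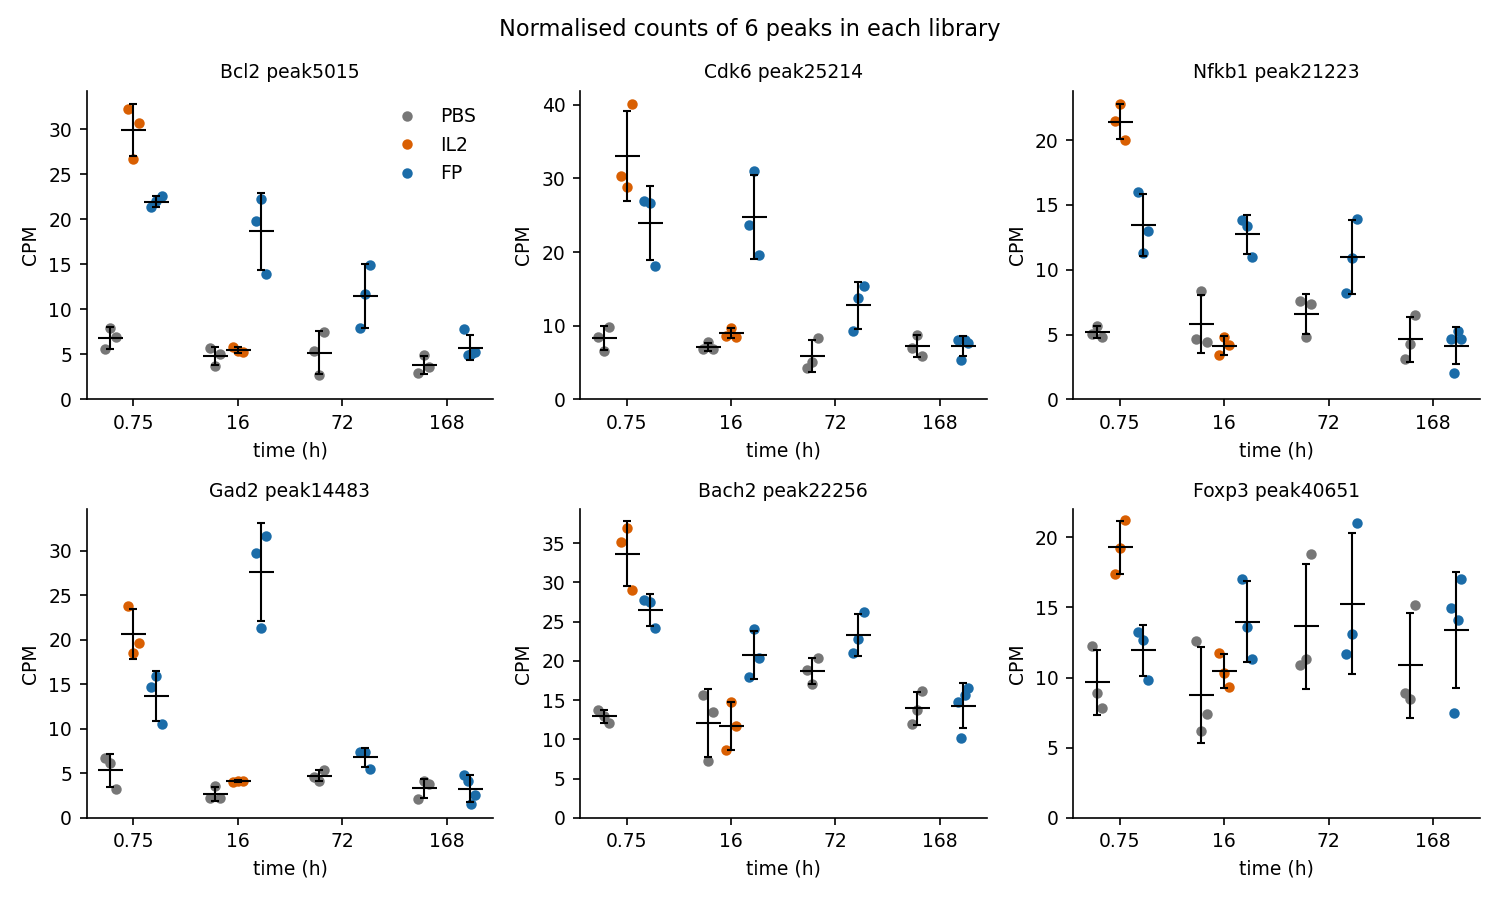
CPM in each library at 6 named peaks, by treatment and time, with points for libraries and bars for group means. At Bcl2 the means were 6.79 (PBS) and 29.9 (IL2) at 0.75 h and 4.79 (PBS), 5.48 (IL2) and 18.7 (FP) at 16 h.

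At 16 h after FP the IL-2 and STAT5 response list shifted up (2 of 208 peaks rose, both at Bcl2; 3 adjusted over the list alone; adjusted p = 6.3e-04, and adjusted p = 0.652 with an estimated correlation). Treg identity (0 rose, 2 alone; adjusted p = 0.0176, and adjusted p = 0.652 with an estimated correlation), resting and lymphoid-homing T cell (0 rose, 0 alone; adjusted p = 0.0142, and adjusted p = 0.794 with an estimated correlation) and NF-kB and TNF receptor peaks (0 rose, 3 alone; adjusted p = 0.0333, and adjusted p = 0.794 with an estimated correlation) shifted up as sets. So did chemokine receptor and trafficking peaks (1 of 186 rose, at Itga4; 11 alone; adjusted p = 0.0246, and adjusted p = 0.652 with an estimated correlation) and constitutive genes (0 rose, 0 alone; adjusted p = 0.0376, and adjusted p = 0.652 with an estimated correlation). Markers of other cells moved beside them: myeloid up (median 0.37, adjusted p = 6.3e-04, and adjusted p = 0.652 with an estimated correlation), erythroid up (median 0.06, adjusted p = 0.00828, and adjusted p = 0.652 with an estimated correlation) and CD8 T cell down (median -0.21, adjusted p = 0.00120, and adjusted p = 0.652 with an estimated correlation). These marker lists had 0 peaks called, and 0, 1 and 0 adjusted over the list alone. On promoter peaks alone the erythroid test pointed downward (median -0.59, adjusted p = 0.115), and so did that of the resting and lymphoid-homing T cell list (median -0.14, adjusted p = 0.307). The NK cell list had a median of 0.53, a mean of -0.29 and an upward test that did not pass (adjusted p = 0.0996), and 1 of its peaks was lower adjusted over the list alone. Of the 115 risen peaks, 98 (85.2%) held the STAT5 consensus, against 7.30% of the others (odds ratio 36.7, 95% interval 21.2 to 63.6; adjusted p = 1.4e-36), and 3.48% lay within 1 kb of a start site (odds ratio 0.101, Fisher's exact test p = 1.6e-10).

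With IL2 at 16 h no peak passed (edgeR; 3645 peaks at an unadjusted p under 0.05; 2 by DESeq2). Bcl2 had a log2 fold change of 0.18 ± 0.27, Nfkb1 -0.48 ± 0.30, Cdk6 0.33 ± 0.24 and Cish 0.11 ± 0.44 (adjusted p = 1 for each; n = 3 each). On simulated data of the same spread and size, 67% of 4-fold and 6% of 2-fold changes were recovered, among peaks with a mean log2 CPM above 1. Of the 18 lists 11 passed by camera, 10 upward and CD8 T cell downward, the strongest being the resting and lymphoid-homing T cell list (median 0.20, adjusted p = 7.0e-05) and the NF-kB and TNF receptor list (median 0.22, adjusted p = 2.4e-04). Every list in this comparison had adjusted p = 0.536 or more with an estimated correlation, and 0 peaks of any list were called, also adjusted over the list alone. Myeloid markers were among the 10 (median 0.27, adjusted p = 0.00832).

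FP and IL2 differed directly at 16 h at 142 peaks in 136 regions, all higher with FP (edgeR; n = 3 each). The named peaks were at Gab2, which encodes a docking adaptor of cytokine receptors (3.17 ± 0.49), Babam2 (3.04 ± 0.48), Fcmr, which encodes the receptor for IgM (2.97 ± 0.48), 1500012K07Rik (4.06 ± 0.71) and Gm43177 (3.44 ± 0.56). Gad2 was higher by 2.74 ± 0.27 (adjusted p = 4.1e-05), Bcl2 by 1.77 ± 0.27 (adjusted p = 0.00387), Cdk6 by 1.47 ± 0.24 (adjusted p = 0.00552) and Nfkb1 by 1.61 ± 0.30 (adjusted p = 0.0222). A peak assigned to Il2rb, the gene of the IL-2 receptor beta chain, was higher by 2.00 ± 0.34 (adjusted p = 0.00989; chromosome 15, 78502386-78503388). The STAT5 consensus was present in 117 of the 142 (82.4%), against 7.29% (odds ratio 29.0, 95% interval 18.6 to 45.3; adjusted p = 1.9e-48), and 2.11% lay within 1 kb of a start site (odds ratio 0.0606, Fisher's exact test p = 6.0e-15). Erythroid markers were higher with FP (1 of 40 peaks rose, at Hbb-bt, 2.00 ± 0.34; 1 adjusted over the list alone; median 0.43; adjusted p = 8.7e-06, and adjusted p = 0.770 with an estimated correlation). Their test pointed downward on promoter peaks alone (median -0.0885, adjusted p = 0.458). AP-1 and immediate early (0 of 137 fell, 0 alone; adjusted p = 0.0117, and adjusted p = 0.962 with an estimated correlation) and cell cycle peaks (2 of 94 rose, at Cdk6, and 2 alone; median -0.20; adjusted p = 0.0117, and adjusted p = 0.770 with an estimated correlation) were lower as sets. The count was 59, 70 and 64 without each IL2 library and 52, 38 and 73 without each FP library (c1, c2 and c3 in turn). It was 62 with library totals as the scaling, 34 with library total as a covariate (added after the data were seen) and 489 by DESeq2. Totals ran from 28.3 to 38.6 M for IL2 and 20.8 to 28.7 M for FP, so this covariate is not well separated from treatment.

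Peaks opened by IL2 at 0.75 h and by FP at 16 h overlapped. Of the 115 peaks that rose with FP at 16 h, 85 had also risen with IL2 at 0.75 h, in comparisons with no shared library. By chance 0.570 would be shared if the calls were independent over the 98884 peaks tested in both. The 490 peaks risen with IL2 at 0.75 h had a median log2 fold change of 1.14 with FP at 16 h (98.0% above 0; fry adjusted p = 5.7e-05) and of 0.04 with IL2 at 16 h (adjusted p = 0.736). With FP at 0.75 h, which shares the PBS libraries used to choose them, their median was 1.10. The test of a change in the FP effect on these peaks from 0.75 h to 16 h gave adjusted p = 0.765. For the 115 peaks risen with FP at 16 h, the IL2 effect was lower at 16 h (median 0.19) than at 0.75 h (median 1.59, adjusted p of the difference = 5.3e-07). Expressed as the mean log2 over PBS per library, the 490 peaks scored 1.86 ± 0.0764 (SD, n = 3) with IL2 and 1.18 ± 0.205 with FP at 0.75 h, 0.02 ± 0.0727 with IL2 and 1.19 ± 0.134 with FP at 16 h, 0.49 ± 0.152 with FP at 72 h and -0.02 ± 0.127 (n = 4) with FP at 168 h. The peaks were chosen for being high in the IL2 and low in the PBS libraries of 0.75 h, which raises the score of IL2 at 0.75 h, its excess over FP and, less directly, the score of FP at 0.75 h. For such scores an exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1.

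**Figure D4:**
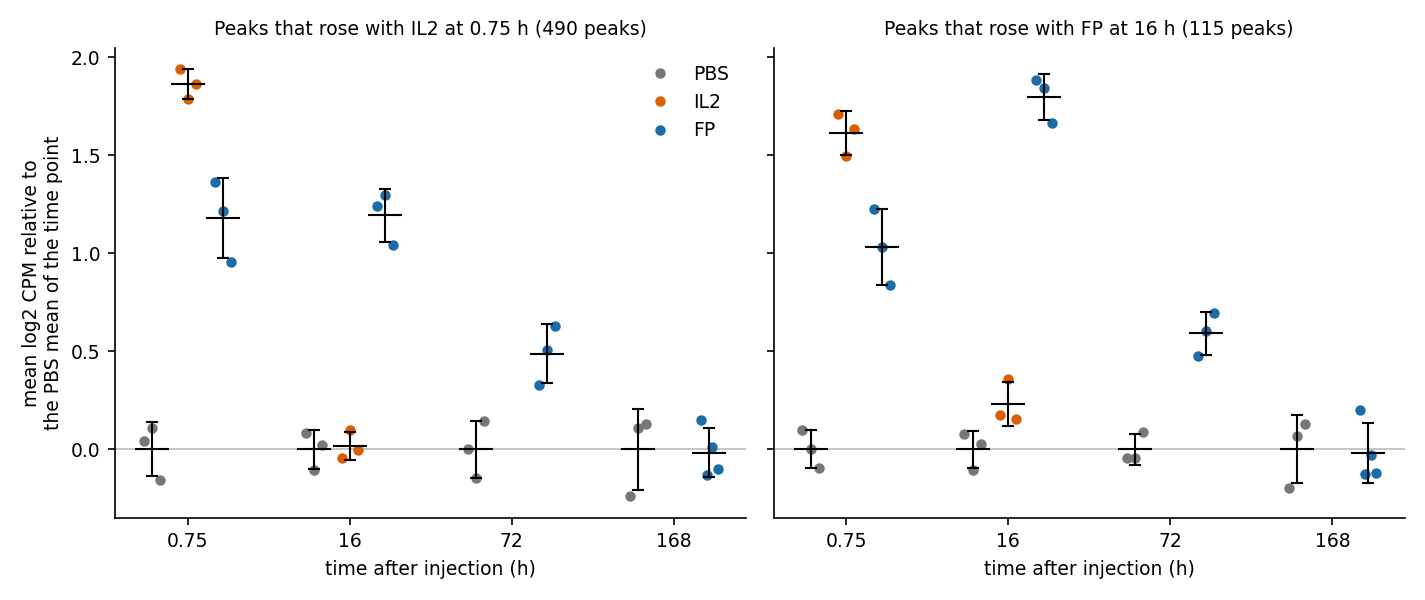
Mean log2 accessibility over PBS of the 490 peaks risen with IL2 at 0.75 h and of the 115 risen with FP at 16 h, per library, by treatment and time in hours. With IL2 the first set falls from 1.86 at 0.75 h, in the libraries used to choose it, to 0.02 at 16 h, and with FP it stands at 1.18, 1.19, 0.49 and -0.02 at 0.75, 16, 72 and 168 h.

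Peak by peak, the IL2 effect differed between 16 h and 0.75 h at 43 peaks, all lower at 16 h (edgeR over all 31 libraries, 104520 peaks tested; 276 by DESeq2). They included Sept9 (-5.79 ± 0.77), Ptpn1 (-3.89 ± 0.63), Lncpint (-3.82 ± 0.73), Nfkb1 (-2.52 ± 0.44) and Gm47635 (-2.52 ± 0.48). Of the 43 peaks, 41 were among the 490 that had risen at 0.75 h, the comparison that also enters this difference. The others were at Grap2 and Gm13982, named because they fell outside that set. The count was 27 and 11 without PBS replicates 1 and 3 at 0.75 h, 12 and 17 without IL2 replicates 1 and 3 at 0.75 h, 22 without PBS library c1 at 16 h, and 14, 28 and 20 without IL2 libraries c1, c2 and c3 at 16 h. The FP effect differed between 72 h and 16 h at 1 peak, Gad2, lower at 72 h (-2.84 ± 0.46; adjusted p = 0.0440; 3108 peaks at an unadjusted p under 0.05; 6 by DESeq2), and this call was absent in 10 of the 12 fits that left out 1 of the 12 libraries of those groups. Between 0.75 h and 16 h (3679 peaks unadjusted; 2 by DESeq2) and between 72 h and 168 h (1522 unadjusted; 0 by DESeq2) the FP effect differed at 0 peaks by edgeR.

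At 72 h after FP no peak passed in the fit of groups alone (edgeR, lowest adjusted p = 0.683; n = 3 each; 5236 peaks at an unadjusted p under 0.05; 141 by DESeq2). Bcl2 had a log2 fold change of 1.13 ± 0.37, Cdk6 1.11 ± 0.31, Cish 1.18 ± 0.38 and Gad2 0.52 ± 0.25 (adjusted p = 0.930 for each). limma's voom with library quality weights, added after the data were seen, called 11699 peaks, with weights of 3.88 for FP replicate 2, 3.67 for PBS replicate 1 and 0.224 for PBS replicate 3. The 490 peaks risen with IL2 at 0.75 h had a median of 0.43 (84.5% above 0; fry adjusted p = 0.0182) and the 115 risen with FP at 16 h one of 0.58 (adjusted p = 0.00330). The effect on the 490 peaks was lower than at 16 h (adjusted p of the difference = 0.00133). Camera placed 10 of 18 lists upward, with the IL-2 and STAT5 response (median 0.22, adjusted p = 1.2e-08), chemokine receptor and trafficking (median 0.18, adjusted p = 2.6e-06) and T cell receptor signalling lists (median 0.17, adjusted p = 1.3e-05) first and myeloid markers (median 0.18, adjusted p = 0.00303) and erythroid markers (median 0.11, adjusted p = 0.0108) among them. Every list had adjusted p = 0.741 or more with an estimated correlation. Over the list alone 0 peaks were called, except 1 lower peak in the NK cell list.

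At 72 h and 168 h many peaks followed the library total (21313 and 19127 with an adjusted p under 0.05 for log2 library total, and 0 at 0.75 h and at 16 h). The total was therefore added to the fit as a covariate, after the data were seen. With it, 85 peaks in 83 regions rose and 42 peaks in 29 regions fell at 72 h after FP, of which 0 were called without it. This count of 127 rests on 3 residual degrees of freedom and on single libraries: it was 42 without PBS replicate 1, 124 without PBS replicate 2, 0 without PBS replicate 3, 8 without FP replicate 1, 0 without FP replicate 2 and 1038 without FP replicate 3. The STAT5 consensus lay in 48 of the 85 risen peaks (56.5%), in 4 of the 42 fallen ones (9.52%) and in 7.39% of the other peaks (odds ratio for rises 16.3, Fisher's exact test p = 5.7e-32). That share too rested on single libraries: it was 71.4% without PBS replicate 1, 66.7% without PBS replicate 2, 33.3% (1 of 3) without FP replicate 1 and 26.5% (178 of 671) without FP replicate 3. The odds ratio of 16.3 is not adjusted for GC content, width and abundance, unlike the STAT5 odds ratios given for the earlier times. On the same measure, in fits with the covariate, the odds ratio was 32.4 for IL2 at 0.75 h and 46.8 for FP at 16 h.

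The peaks called with the covariate at 72 h included the Gab2 peak that was higher with FP than with IL2 at 16 h (2.30 ± 0.28; adjusted p = 0.00243; chromosome 7, 97209893-97210619). It had 5.60 to 6.79 CPM in the 3 FP libraries and 0.952 to 1.76 CPM in the 3 PBS libraries. Other rises were at Zfp652, which encodes a zinc-finger factor (2.63 ± 0.43), Pigz (2.19 ± 0.36), Tspan14, which encodes a tetraspanin (1.92 ± 0.29), and Nfatc2, which encodes an NFAT factor of T cell activation (1.43 ± 0.25). The chromosome 1 peak that held 24.0% of all counts, assigned to Gm10222, was among the rises too (0.23 ± 0.03; edgeR adjusted p = 0.00243). Its share of counts ranged from 15.0% to 32.2% between libraries. Whether its reads come from this locus alone was not tested, so it is not read as chromatin that opened. Falls included Hdac9, which encodes a histone deacetylase (-2.09 ± 0.35), and Gm37831 (-1.82 ± 0.25). Bcl2 did not pass with the covariate (0.93 ± 0.22; adjusted p = 0.0939, and 0.0157 to 1.00 over its 18 alternatives). Of the 85 risen peaks 15 were among the 490 risen with IL2 at 0.75 h and 10 among the 115 risen with FP at 16 h. At 168 h 10 peaks in 7 regions rose with the covariate. Of these, 9 were abundant peaks assigned to Gm10800, Gm21738, Gm33838 and Gm10722, with rises of 0.51 to 0.64. Whether the reads at these 9 come from single loci was not tested, so they are not read as genes that opened. The other was at Pygl, which encodes a glycogen phosphorylase (2.01 ± 0.32). The count of 10 became 16 without PBS replicate 1 and 0 without PBS replicate 4 or FP replicate 2. The STAT5 consensus lay in 1 of these 10 peaks (10%) and in 7.27% of the other peaks (odds ratio 1.42, Fisher's exact test p = 0.530). Of the 10 peaks, 0 were among the 490 or the 115.

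At 168 h after FP no peak passed without that covariate either (edgeR, lowest adjusted p = 0.899; FP n = 4, PBS n = 3; 4658 peaks at an unadjusted p under 0.05; 11 by DESeq2; 0 by voom with quality weights). Bcl2 had 0.59 ± 0.32, Prdm1, which encodes a factor of effector differentiation, 0.69 ± 0.26, and Tcf7, which encodes a factor of resting T cells, 0.71 ± 0.27 (adjusted p = 0.899 for each). The 490 peaks had a median of -0.01 (fry adjusted p = 0.910), lower than at 16 h (adjusted p of the difference = 2.9e-06) and than at 72 h (adjusted p = 0.00848). Camera placed 10 lists upward, first NF-kB and TNF receptor (median 0.35, adjusted p = 6.2e-11), IL-2 and STAT5 response (median 0.24, adjusted p = 1.2e-06), interferon response (median 0.46, adjusted p = 2.7e-06) and constitutive genes (median 0.26, adjusted p = 6.2e-04), and B cell (median -0.13) and erythroid cell markers (median -0.20) downward (adjusted p = 0.0259 and adjusted p = 0.0299). On promoter peaks alone the erythroid test pointed upward (median 0.22, adjusted p = 0.713). Every list had adjusted p = 0.691 or more with an estimated correlation, and 0 peaks were called over any list alone. The libraries that stood apart belong to this time point.

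Across peaks, which are not independent replicates, the edgeR log2 fold changes of FP and IL2 against their shared PBS libraries correlated at r = 0.512 at 0.75 h and 0.479 at 16 h. For the simulation, effects were taken as differences of group mean log2 CPM, which gave r = 0.526 at 0.75 h. With no effect simulated and the PBS libraries shared, the correlation was 0.509 and the covariance 0.174, against a measured covariance of 0.185. At 16 h the measured r on that scale was 0.494 against a simulated 0.516, with covariances of 0.167 and 0.164. The highest of the 20 simulated covariances was 0.176 at 0.75 h and 0.166 at 16 h. The measured ones lay above what the shared libraries gave in simulation, by 0.0109 and 0.00307 over the mean. The simulated peaks varied independently, while real peaks overlap and can share trends of a library. The spread of the 20 draws is therefore too narrow to judge this excess, and no conclusion is drawn from it. At 0.75 h both FP calls were among the 490 peaks risen with IL2, where 0.00975 would be shared if the calls were independent. PBS groups of 3 libraries cannot be split between the comparisons, so part of that overlap may come from the shared controls. Without shared libraries, the correlation of edgeR log2 fold changes was 0.157 between IL2 at 0.75 h and FP at 16 h, 0.161 between FP at 16 h and at 72 h, and 0.393 between FP at 72 h and at 168 h. With library total as a covariate in both fits these correlations were 0.0282, 0.0445 and 0.169, and FP groups had the higher mean totals at 72 h and 168 h, so the 0.393 is not free of the trend with library total.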

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

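In this part the tests chosen only after the result was seen were voom with quality weights, the fits with library total as a covariate, the bound of 2 SE used for the later times, and the limits by which the share of risen peaks with the STAT5 consensus was weighed as an explanation, while the motif test itself was planned. Within the group of 4 libraries (FP at 168 h), 2 values lay far from the others by Dixon's ratio, out of 18 quantities examined, where chance gives about 1 in 20 groups. The Myc peak stood at 7.44 CPM in FP replicate 2, below 17.0 to 17.5 in the other 3 libraries (ratio 0.955), and the Bcl2 peak stood at 7.82 CPM in FP replicate 1, above 4.93 to 5.27 (ratio 0.882). FP replicate 2 had 12.3 M counts, against 32.8 to 37.7 M in the other 3.

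Effects that differed between times, each tested as a difference, were looked at again. The IL2 effect was lower at 16 h than at 0.75 h at 43 peaks, among them Sept9 (-5.79), Ptpn1 (-3.89), Lncpint (-3.82), Nfkb1 (-2.52) and Gm47635 (-2.52). The FP effect was lower at 72 h than at 16 h at 1 peak, Gad2 (-2.84). Over the 490 peaks risen with IL2 at 0.75 h, the FP effect differed between 72 h and 16 h (fry adjusted p = 0.00133), 168 h and 72 h (adjusted p = 0.00848) and 168 h and 16 h (adjusted p = 2.9e-06). Over the 115 peaks risen with FP at 16 h, the IL2 effect differed between 16 h and 0.75 h (adjusted p = 5.3e-07) and the FP effect between 168 h and 72 h (adjusted p = 0.00177). Time points differ also in date, and a date that changed the response, rather than the level, cannot be told apart from time.

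FP at 0.75 h called far fewer peaks than IL2 (2 against 499). The gap was smaller by DESeq2 and with replicate number as a block, as given in the part on how the results depend on the processing. Without FP replicate 3, 25 peaks were called for FP. The limit fixed in advance, a share of the 499, was strict for a fit with 1 library fewer. IL2 itself missed it without PBS replicate 3, with 187 peaks. As 25 is far below 187, noise from FP replicate 3 alone is argued against for the whole gap. The rise from 2 to 25 leaves open that it adds a part. At the 115 peaks risen with FP at 16 h, FP lay below IL2 at 0.75 h by a median of -0.54 (-0.65 to -0.48 when each library was left out in turn), so a smaller rise under FP may explain part of the difference. The dose and the protein changed together, and no test here separates them.

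FP called 0 peaks at 72 h and at 168 h by edgeR (5236 and 4658 at an unadjusted p under 0.05; 141 and 11 by DESeq2; 11699 and 0 by voom with quality weights). With library total as a covariate 127 peaks were called at 72 h (0 without PBS replicate 3 or FP replicate 2, 8 without FP replicate 1, 42 without PBS replicate 1, 1038 without FP replicate 3) and 10 at 168 h (0 without PBS replicate 4 or FP replicate 2, 16 without PBS replicate 1), so spread that follows library totals may have hidden changes, and the counts of 0 do not show that chromatin was back at the PBS level. Of the 10 peaks at 168 h, 1 held the STAT5 consensus (10%, against 7.27% of the other peaks) and 0 were among the 490. They are weak grounds for hidden changes at that time. Noise that hid a rise as large as at 16 h is argued against: the 490 peaks had a median of 0.43 at 72 h and -0.0148 at 168 h, against 1.14 at 16 h. Their mean scores per library differed between FP and PBS by 0.488 ± 0.122 (SE), -0.0168 ± 0.136 and 1.19 ± 0.0957 at these times. At 72 h the median lies below 0.569, 0.5 of the value at 16 h, by little more than the SE of the scores, so a rise of that size stays open. With the covariate the medians at 72 h and 168 h were 0.41 and -0.07.

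Rises outnumbered falls among the called peaks for IL2 at 0.75 h and FP at 16 h. At an unadjusted p under 0.05 by edgeR the split was more even. It was 3556 rises and 2209 falls for IL2 at 0.75 h, and 3158 and 2192 for FP at 16 h. Scaling is argued against, since under 3 other scalings at most 2.02% of called peaks were falls for IL2 at 0.75 h and 0% for FP at 16 h. GC content is argued against too, since 99.4% of the peaks called for IL2 at 0.75 h stayed called with a GC offset. The STAT5 consensus lay in 70.6% of the peaks risen with IL2 at 0.75 h and, in other libraries, in 85.2% of those risen with FP at 16 h. Binding at such sites may have opened the chromatin, which stays a hypothesis, since binding was not measured here.

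Treatment labels were also reassigned among the same libraries. For 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real and highest other counts were 499 and 0 for IL2 at 0.75 h, 2 and 3 for FP at 0.75 h, 0 and 0 for FP against IL2 at 0.75 h, 115 and 0 for FP at 16 h, 0 and 16 for IL2 at 16 h, and 142 and 1 for FP against IL2 at 16 h. At 72 h the real count was 0 and the highest other 14917, with PBS replicates 1 and 2 and FP replicate 1 (20.0 to 29.7 M counts) against the other 3 libraries (46.2 to 59.6 M). At 168 h all 35 splits called at least the real count of 0, and the highest called 22312, with PBS replicates 1 and 2 and FP replicate 2 (7.39 to 13.4 M) against the other 4 libraries (32.8 to 37.7 M). Both point to a structure of the samples that follows library totals. With library total as a covariate 21313 peaks followed it at 72 h and 19127 at 168 h, and 0 did at 0.75 h and at 16 h. In those fits the real count was 127 and the highest other 1 at 72 h, again with 10 splits, and at 168 h the real count of 10 was reached by 1 of 35 splits, itself (highest other 7).

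For the differences between times 40 assignments each were used, on the libraries of the groups involved. For the IL2 effect at 16 h against 0.75 h the real assignment called 31 peaks, 2 of 40 called as many, and the highest other called 35, so by this count chance is not excluded at 0.05. That assignment kept the real groups at 0.75 h and so contains the effect of that time. The highest among those that broke up these groups was 5. For the FP effect at 72 h against 16 h the real assignment called 1 and 7 of 40 called as many. Its highest other called 7701, the structure seen at 72 h. For the FP effect at 16 h against 0.75 h and at 168 h against 72 h all 40 called at least the real count of 0, with highest others of 158 and 3812.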

How the results depend on the processing

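In this part voom with quality weights, 1 peak per overlapping region, the fits without the libraries that stand apart, the covariate for library total and the sets (with and without the STAT5 consensus) were chosen only after the result was seen. The count for FP at 0.75 h, 2 peaks, was 5 with library totals, 16 with an abundance offset, 13 with a GC offset, 10 without the low-count filter, 14 with 1 peak per overlapping region, 210 by DESeq2, and 0 with the 2 groups only, with all 31 libraries in one fit and with library total as a covariate. At an unadjusted p under 0.05 it was 3160. With library total as a covariate the Bcl2 and Gm47635 peaks kept log2 fold changes of 1.88 ± 0.28 and 1.74 ± 0.29, against 1.69 ± 0.22 and 1.80 ± 0.23 without it, and no longer passed (adjusted p = 0.391 for each, the highest of 22 alternatives, with 1.1e-09 and 7.8e-10 by DESeq2 the lowest). The count of IL2 at 0.75 h (499) was 1116 by DESeq2, 286 with the covariate, 283 of them among the 499, and 5765 unadjusted. Its 9 falls became 0 with the covariate.

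For FP at 16 h the count of 115 was 54 with library totals, 194 with the 2 groups only, 452 by DESeq2, 271 by voom and 5350 unadjusted. With the covariate it was 80, of which 58 were among the 115. For FP against IL2 at 16 h, 142 became 62 with library totals, 489 by DESeq2, 34 with the covariate and 5087 unadjusted. IL2 at 16 h, with 0, had 2 by DESeq2 and 3645 unadjusted. FP against IL2 at 0.75 h, also 0, had 6 by DESeq2 and 3677 unadjusted. FP at 72 h, at 0, had 141 by DESeq2, 11699 by voom, 127 with the covariate and 5236 unadjusted. FP at 168 h, at 0, had 11 by DESeq2, 10 with the covariate and 4658 unadjusted. With the covariate, leaving out each library gave 0 to 1038 at 72 h (PBS 1 42, PBS 2 124, PBS 3 0, FP 1 8, FP 2 0, FP 3 1038) and 0 to 16 at 168 h (PBS 1 16, PBS 4 0, FP 2 0). The cause was not tested. The covariate takes up spread that follows library totals. At 0.75 h and 16 h 0 peaks followed them, so lower counts there do not show such spread.

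For effects between times, the FP effect at 16 h against 0.75 h (0 peaks) had 2 by DESeq2. The FP effect at 72 h against 16 h (1 peak) had 0 with library totals and 6 by DESeq2. The IL2 effect at 16 h against 0.75 h (43 peaks) had 25 with library totals, 79 with the 2 time points only, 97 without the libraries that stand apart and 276 by DESeq2. The cause was not tested.

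Leaving out each library in turn gave 0 to 25 peaks for FP at 0.75 h (0 without any of PBS replicates 1, 2 and 3, IL2 replicates 1 and 3 and FP replicate 2, 1, a fall, without FP replicate 1, 25 without FP replicate 3) and 187 to 591 for IL2 at 0.75 h (220 without PBS replicate 1, 187 without PBS replicate 3, 207 without IL2 replicate 1, 202 without IL2 replicate 3). It gave 37 to 143 for FP at 16 h (PBS c1 48, c2 61, c3 51; FP c1 37, c2 39, c3 66) and 38 to 180 for FP against IL2 at 16 h (IL2 c1 59, c2 70, c3 64; FP c1 52, c2 38, c3 73). IL2 at 16 h, FP against IL2 at 0.75 h, FP at 72 h, FP at 168 h and the FP effects at 16 h against 0.75 h and at 168 h against 72 h stayed at 0 to 0 by edgeR. The FP effect at 72 h against 16 h ran from 0 to 1, with 0 in 10 of 12 fits. The IL2 effect at 16 h against 0.75 h ran from 11 to 52 (at 0.75 h, PBS 1 27, PBS 3 11, IL2 1 12, IL2 3 17; at 16 h, PBS c1 22, IL2 c1 14, c2 28, c3 20).

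The median log2 fold change of the 490 peaks risen with IL2 at 0.75 h ran over the same fits from 1.01 to 1.23 for FP at 0.75 h, 1.11 to 1.19 for FP at 16 h, 0.35 to 0.55 at 72 h, -0.11 to 0.05 at 168 h, 1.72 to 1.83 for IL2 at 0.75 h, -0.03 to 0.09 for IL2 at 16 h, -0.73 to -0.56 for FP against IL2 at 0.75 h and 1.05 to 1.19 at 16 h. For the 115 peaks risen with FP at 16 h the ranges, in the same order, were 0.88 to 1.14, 1.60 to 1.72, 0.51 to 0.61, -0.14 to 0.04, 1.53 to 1.65, 0.12 to 0.25, -0.65 to -0.48 and 1.41 to 1.58. Without the members that hold the STAT5 consensus the 490 peaks had 0.93 for FP at 16 h and 0.95 for FP against IL2 at 16 h, and the 115 peaks 2.02 and 1.67. The 115 peaks were chosen on the FP libraries of 16 h, so the choice sets their 2.02 and 1.67 high and these values say nothing about stability. The same holds for any median of a set in a comparison that contains libraries used to choose it. With library total as a covariate, the correlation of effects across peaks was 0.585 between FP and IL2 at 0.75 h and 0.753 at 16 h, where both share the fitted trend, 0.0282 between FP at 16 h and IL2 at 0.75 h, 0.0445 between FP at 16 h and 72 h, and 0.169 between FP at 72 h and 168 h. The cause of the other changes was not tested.

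Named peaks that passed (43 results) had 931 alternatives, in which 762 calls stayed, 169 were lost and 0 changed sign. Of the 78 named results that did not pass, 16 of 1605 alternatives passed, among them Foxp3 for IL2 at 0.75 h with the replicate block (1.02) and by DESeq2 (0.98). In 74 of the 1605 the log2 fold change had the other sign than in the main fit.

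Gene lists depended on the assumed correlation between peaks: with an estimated correlation 0 lists passed in each of the 8 comparisons. On promoter peaks only, 2 lists passed for FP at 16 h, 6 for FP at 72 h, 6 for IL2 at 16 h and 1 for FP against IL2 at 0.75 h, and with an abundance offset 7 passed for IL2 at 16 h. On promoter peaks only the test of erythroid markers turned downward for FP at 0.75 h (median -0.17), FP at 16 h (-0.59) and FP against IL2 at 0.75 h (-0.18) and at 16 h (-0.0885), and upward for FP at 168 h (0.22). The resting and lymphoid-homing T cell test turned downward for FP at 16 h (-0.14) and IL2 at 0.75 h (-0.0724). For distal peaks only, the motif odds ratios that moved were NFAT 1.05 and KLF 0.899 for FP at 16 h, and NFAT 0.736 (no longer past the threshold) and NF-kB 0.564 (newly past it) for IL2 at 0.75 h. The cause was not tested.

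With replicate number as a block, FP at 0.75 h called 129 peaks and IL2 at 0.75 h 983 (941 rises and 42 falls), while FP against IL2 at 0.75 h, FP at 72 h and FP at 168 h called 0 by edgeR. After the group means were removed, libraries of the same number correlated at 0.00379 to 0.242 at 0.75 h (mean 0.117 over 9 pairs), -0.190 to 0.584 at 72 h (mean 0.199) and -0.228 to 0.416 at 168 h (mean 0.143). Libraries of different numbers ran from -0.235 to 0.0612 at 0.75 h (mean -0.0583 over 18 pairs), -0.665 to 0.578 at 72 h (mean -0.103) and -0.600 to 0.437 at 168 h (mean -0.0545). At 0.75 h every library numbered 2 or 3 correlated best with its own number in both other groups. Number 1 was mixed: PBS replicate 1 had 0.0437 with FP replicate 3 and 0.00379 with FP replicate 1. Same-number libraries may share something unnamed in the labels, so pairing at 0.75 h stays open. Deviations within a group sum to 0, so the different-number values are not separate evidence. The labels tie the numbers to no animal, batch or day, so the planned fit without the block was kept as the main one. At 16 h no block was fitted, since the titles of the 3 groups share no number and the columns carry other numbers.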

Other observations

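Several genes held more than 1 called peak. At 0.75 h after IL2 there were 10 called peaks at Aven, 10 at Jazf1 and 7 at Man1a, at 16 h after FP 4 at Man1a, and for FP against IL2 at 16 h 7 at Lrpap1. Some of these peaks overlap and are not separate regions.

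Further peaks at which the IL2 effect was lower at 16 h than at 0.75 h were at Ikzf3, which encodes the transcription factor Aiolos (-4.16 ± 0.75), Fhit (-2.96 ± 0.38; adjusted p = 5.2e-04), Traf6, which encodes an adaptor of TNF receptor and interleukin-1 receptor signalling (-2.26), the noncoding RNA gene Pvt1 (-3.21), Kcnj15 (-4.85) and Nampt, which encodes an enzyme of NAD synthesis (-3.17). They were picked after their values were seen.

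Of 144 list tests, 30 had a median, a mean and a test direction that differed in sign, and 0 of these passed the threshold.

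The peak assigned to Gm10800 (chromosome 2, 98666204-98667298, GRCm38) held 6.76% of all counts. It fell by -0.22 at 0.75 h after IL2 and rose by 0.51 at 168 h after FP with library total as a covariate, small changes at a very abundant peak whose standard errors (0.05 and 0.05) are small as well. Whether its reads come from this locus alone was not tested, so neither change is read as chromatin that closed or opened.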
